A study of Mus musculus with 6 samples.

How the data were processed

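Total RNA from the proximal colon of 6 mice was measured on 6 Affymetrix-type mouse expression arrays, 3 from wild-type mice and 3 from mice heterozygous for a gene trap in Mthfd1. Per the labels, the mice were 8 weeks old and had eaten a defined control diet for 5 weeks, and the RNA was amplified and labelled with biotin before hybridisation. Each array is a separate animal of its group by its title. Strain, sex, the site of the trap within the gene and the time of day of collection are not given in the sources used here.

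The deposited values are linear intensities, 1 per probe set and array, without background or detection columns. GCOS, the array maker's scanning and expression software, is named in the submitters' processing notes, and its version and settings are not given in the sources used here. A test of the deposited intensities showed that the mean of each array, after the top and bottom 2% of probe sets were left out, was 500, so the arrays had been scaled to 1 common level. Median intensity ran from 156.85 to 168.25. The number of arrays, 3 per genotype, limits the precision of every comparison. Because scaling to a common mean fixes the level of each array, a change in total RNA per cell is not measurable.

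Of 22690 probe sets, 64 were controls and were left out. Gene names came from the platform's annotation, updated through gene numbers of the GRCm38.p6 gene table, which altered 0 symbols. Among the remaining probe sets, 20380 had 1 gene symbol, 691 had several and 1555 had none in that table. Genes were not named from a probe set with several symbols.

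Intensities entered as log2(signal + 16), so fold changes of dim genes are understated. The medians of the log2 values differed by 0.09 between arrays, under the bound of 0.3 set beforehand, and the arrays were therefore used as deposited. Probe sets with a mean below the 40th percentile were left out, which left 13576 tested probe sets and 8241 genes. The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene was represented by its brightest probe set with 1 symbol. Single values were compared by an exact two-sided permutation test of the difference in means, for which 0.1 is the smallest p that 3 against 3 arrays can give.

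The 37 gene lists were fixed before the data were examined, and so were the tests, the alternatives and the rule for naming genes. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 32 lists with at least 5 measured genes, and again with an estimated correlation and with fry. Member genes were also adjusted over the list alone, which takes no account of the number of lists or of genes outside the list. The genes named are Mthfd1, the 12 genes in each direction that had the largest change past the threshold and groups that did not overlap, and up to 3 members of each list by smallest p. Places left open were filled by the smallest p among genes whose groups did not overlap, which applied to all of them here. Genes named outside the rule are said to be so. Genes within 20 Mb of Mthfd1 were compared with 10000 random windows holding as many neighbouring genes, by mean absolute t, one-sided for a larger mean. Gene positions and distances came from the GRCm38.p6 gene table, which also served for the names above.

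The steps were tested on data simulated from the means and variances of these arrays, with genes altered by known folds. For the comparison of heterozygous with wild-type arrays over 13576 probe sets, 30.2% of probe sets altered 1.5-fold, 89.1% of those altered 2-fold and 98.2% of those altered 4-fold were called, with 11 false calls among 143. The simulated noise was independent between genes, which real arrays do not offer. The simulation also altered 63, 64 and 57 tested probe sets at once by the 3 folds, and many true changes make the adjusted threshold easier to pass. The shares called therefore do not carry over to the real comparison, which had 0 calls. There, Tspan4 at log2 -1.09 had a limma adjusted p of 0.0673, so 0 calls do not show that 2-fold changes are absent.

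Alternatives covered the normalization, pseudocount, filter, variance model, array weights, replicate number as a block, each array left out in turn, the thresholds, the set test and the width of the window. A score of ileal genes as a covariate, and probe sets in place of genes near Mthfd1, were added after seeing the data.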

Results

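Gene expression was measured in the proximal colon of 3 wild-type mice and 3 mice heterozygous for a gene trap in Mthfd1, which encodes a cytosolic enzyme of 3 activities that interconverts folate-bound one-carbon units for purine and thymidylate synthesis. The series addresses Mthfd1 as a modifier of intestinal tumour formation, and the comparison asks how the untreated colon differs between the genotypes. Arrays correlated at r = 0.959 to 0.981 across probe sets within a genotype and at 0.961 to 0.982 between genotypes. These correlations are across genes, which are not independent replicates.

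Mthfd1 signal was lower in every heterozygous array than in every wild-type array at each of its 3 probe sets. The brightest probe set read 890 ± 56.1 (SD, n = 3) in wild-type and 504 ± 48.4 (SD, n = 3) in heterozygous colon, 56.6% of the wild-type mean (log2 fold change -0.80, SE 0.12). The next brightest read 421 ± 19.7 (SD, n = 3) and 206 ± 34.5 (SD, n = 3), or 49.0% of wild-type (log2 fold change -0.99, SE 0.15). The dimmest, below the filter, read 54.4 ± 9.06 and 34.6 ± 2.85. Each gave an exact permutation p of 0.1, the smallest possible with 3 against 3 arrays. The limma adjusted p over all probe sets was 0.121 and 0.108 for the brighter 2, so neither passed over all genes, whereas Mthfd1 fell when adjusted over the folate list alone (adjusted p = 0.0015, limma). The part of the transcript that the trap removes is not given in the sources used here, so the probe sets check the labels only if they lie downstream of it.

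**Figure D1:**
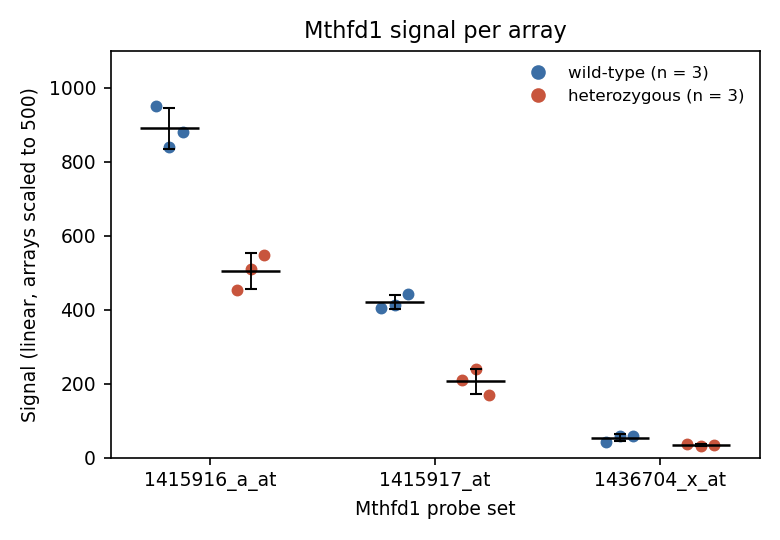
Linear signal of the 3 Mthfd1 probe sets in each array, with wild-type arrays in blue and heterozygous arrays in red; lines are means and error bars SD (n = 3). At the brightest probe set, on the left, the heterozygous arrays lie between 453.1 and 549.4, below all wild-type arrays, which lie between 838.6 and 949.9.

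No single gene outside the lists' own adjustment passed the threshold. Of 13576 probe sets, 0 had a limma adjusted p under 0.05 (smallest 0.054), and 772 had an unadjusted p under 0.05, of which 424 were higher and 348 lower in heterozygous colon, where chance alone gives 679. The groups did not overlap for 878 genes, or 10.7%, against 10% by chance. The genes nearest to the threshold were Ifit1, an interferon-induced RNA-binding protein, with 352 ± 111 (SD, n = 3) in wild-type and 1343 ± 210 (SD, n = 3) in heterozygous colon (log2 fold change 1.91, SE 0.21), and Rtp4, also interferon-inducible, with 403 ± 65.7 and 1590 ± 432 (log2 1.91, SE 0.21), both at adjusted p = 0.054. With 1 probe set per gene tested, these 2 genes passed (adjusted p = 0.0356, limma). The count of probe sets past the threshold was 39 without heterozygous replicate 1 and 2 without wild-type replicate 3, and 439 rather than 772 had an unadjusted p under 0.05 without heterozygous replicate 3.

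Further genes with higher values in all 3 heterozygous arrays were Rsad2 (log2 fold change 1.45), Gbp6 (1.29), Ddx60 (1.57), Oasl2 (2.28), Parp14 (0.99), Trim34a (0.99), Ifi27l2b (0.94) and the chemokine Cxcl9 (2.01). Me1, malic enzyme, had a log2 fold change of 0.74, and Fasn, fatty acid synthase, read 1987 ± 143 in wild-type and 2905 ± 35.4 in heterozygous colon (SD, n = 3 each; log2 0.55). Genes with lower values in all 3 heterozygous arrays, besides Mthfd1, were the tetraspanin Tspan4 (316 and 140, log2 -1.09, SE 0.14), the T-cell receptor kinase Zap70 (453 and 141, log2 -1.64, SE 0.24), Dcaf8 (-0.91), Dnase2a (-0.60), the clock output gene Dbp (-1.29), Ttc39c (-0.83), Jund (-0.51), Plcg2 (-0.58), Stard3 (-0.47), Hif1a (-0.49) and Hspb1 (-0.49). None of these passed over all probe sets, with limma adjusted p between 0.0673 and 0.608. They are the genes picked by the naming rule and not a full list, since the groups did not overlap for 878 genes. Another probe set of Zap70, below the filter and not shown to be above background, was higher in all 3 heterozygous arrays (means 10.6 and 44.7), so the direction of Zap70 rests on 1 probe set.

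Interferon-response genes were higher as a group in heterozygous colon. All 22 measured members had a positive fold change, with a median log2 of 0.94, and 17 of the 22 rose when adjusted over the list alone, against 0 over all genes. Besides Ifit1, Rsad2, Oasl2 and Cxcl9, Tap1, a peptide transporter for antigen presentation, rose from 132 ± 21.1 to 312 ± 122 (SD, n = 3 each; log2 1.10, SE 0.25). The mean of the list's centred log2 values was -0.50, -0.71 and -0.35 in the wild-type arrays and -0.02, 0.63 and 0.96 in the heterozygous arrays (exact permutation p = 0.1). The list passed camera in limma (adjusted p = 2.4e-26) and did not pass with an estimated correlation between its genes (adjusted p = 0.612) or with fry (adjusted p = 0.536). In all, 8 of 32 lists passed camera, 0 passed with an estimated correlation or with fry, and 6 of the 10 splits of the 6 arrays gave at least 8. Among the 8, the estimated correlation ran from 0.00072 for the clock list to 0.79 for antigen presentation, against the preset 0.01. It was 0.58 for the interferon list.

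**Figure D2:**
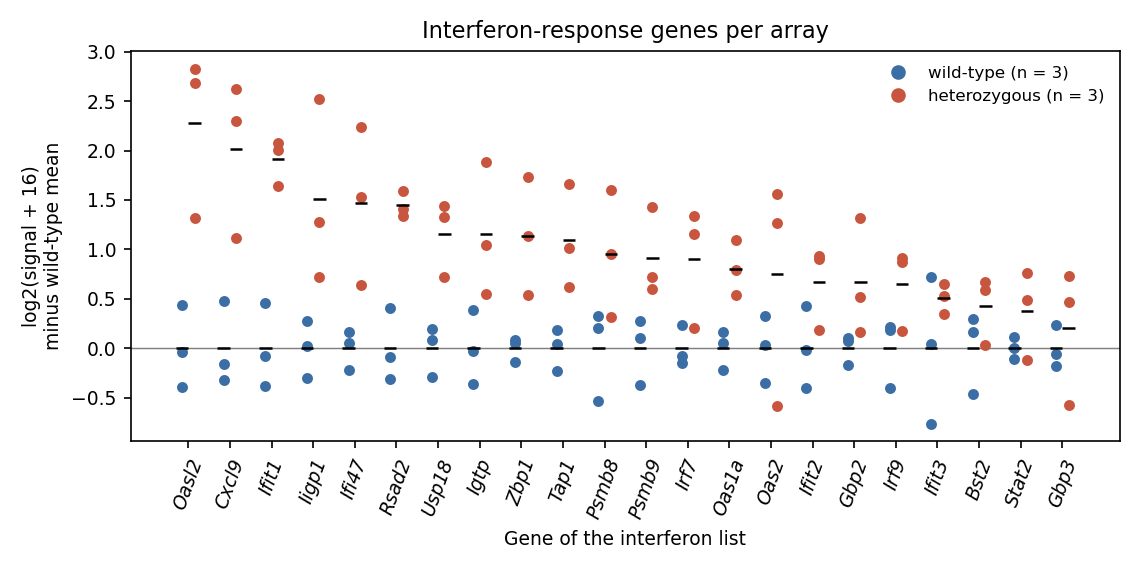
The 22 measured interferon-response genes, each as log2(signal + 16) minus its wild-type mean; points are single arrays (n = 3 per genotype) and black lines are group means. Means of the heterozygous arrays lie above those of the wild-type arrays for all 22 genes, by 0.21 to 2.28, the last for Oasl2.

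Antigen presentation genes were higher alongside them. All 12 measured members of the list of major histocompatibility class II and antigen presentation genes had positive fold changes (median log2 0.44), and 8 rose when adjusted over the list alone, among them the class II chains H2-Aa (2808 ± 255 and 4630.4 ± 1305, SD, n = 3 each; log2 0.69) and H2-Eb1 (log2 0.57). Without heterozygous replicate 3 the median was 0.24. The 2 lists share 1 measured gene, Tap1. Macrophage and dendritic cell markers had a median log2 of 0.26, with 14 of 17 positive and 0 that passed adjusted over the list alone; Itgax had 0.60, Fcer1g 0.53 and Cd14 0.45. That median was 0.13 without heterozygous replicate 3 and 0.16 without wild-type replicate 3. Cd14 was highest in heterozygous replicate 3, at 1156.7, against 699.1 and 794.9 in heterozygous replicates 1 and 2. Of 7 measured T-cell genes, Il7r (0.58), Cd3d (0.92) and Ccl5 (1.95) rose and Zap70 fell at its tested probe set, with the other of opposite sign, when adjusted over the list alone; Ccl5 is named as the last of those that passed. The T-cell score was 0.62 and 0.84 in heterozygous replicates 2 and 3, and -0.53 in heterozygous replicate 1, the lowest of the 6 arrays (exact permutation p = 0.4); the list's median log2 was 0.65, 1.02 without heterozygous replicate 1 and 0.39 without the filter. Without heterozygous replicate 1, Ccl5 was 2.97, and without heterozygous replicate 3, Ccl5 was 1.29 and Cd3d 0.60. Cd3d overlapped between the groups, at 109.5 in heterozygous replicate 1 and 109.8 in wild-type replicate 3. The 3 lists passed camera (limma adjusted p = 9.78e-12, 1.78e-04 and 0.0304) and none passed with an estimated correlation (adjusted p = 0.612 for each). The T-cell call ended without wild-type replicate 1 or 3 or heterozygous replicate 2 or 3 (adjusted p = 0.0639, 0.0962, 0.279 and 0.204), with the robust variance (0.215), and has no test at the 60th percentile filter.

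Cholesterol synthesis genes were lower, with 17 of 18 members negative and a median log2 of -0.33 (camera in limma, adjusted p = 2.72e-07; adjusted p = 0.612 with an estimated correlation). None passed adjusted over the list alone. The list's score was 0.18, 0.04 and 0.26 in the wild-type arrays and 0.11, -0.24 and -0.36 in the heterozygous arrays, which overlap (exact permutation p = 0.2). Squalene epoxidase Sqle read 1422 ± 156 in wild-type and 1011 ± 212 in heterozygous colon (SD, n = 3 each; log2 -0.50), Hsd17b7 had a log2 fold change of -0.44 and Cyp51 of -0.57. Fatty acid oxidation and ketogenesis genes had a median log2 of 0.15, with 16 of 20 positive and 0 that passed adjusted over the list alone; Slc25a20, the mitochondrial carnitine carrier, had 0.24, Pdk4 0.94 and Hadhb 0.20. Pdk4 overlapped between the groups and was 1.61 without heterozygous replicate 1 and 0.51 without heterozygous replicate 2. The list's score was -0.09, 0.09 and -0.23 in the wild-type arrays and -0.14, 0.21 and 0.17 in the heterozygous arrays (exact permutation p = 0.3). That list passed camera at adjusted p = 0.0303 (limma) and not with an estimated correlation (adjusted p = 0.779), and its call ended without wild-type replicate 3 (0.690) or heterozygous replicate 2 (0.311) or 3 (0.0871), without the filter, without a variance trend, with array weights and with the mean of all probe sets. The median was 0.26 without wild-type replicate 2, 0.05 without wild-type replicate 3, 0.23 without heterozygous replicate 1 and 0.08 without heterozygous replicate 2 or 3. Another probe set of Hadhb had the opposite sign.

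Proliferation genes had a median log2 of 0.20, with 28 of 31 positive and 0 that passed adjusted over the list alone. The proliferation marker Mki67 read 1039 ± 234 and 1395 ± 123 (SD, n = 3 each; log2 0.44), Bub1 had a log2 fold change of 0.97 and Top2a of 0.44. Bub1 and Top2a overlapped between the groups, with wild-type replicate 1 at 240.5 and 973.3 and heterozygous replicate 1 at 237.6 and 926.9. Mki67 was 1280.5 in wild-type replicate 1 and 1290.7 in heterozygous replicate 2. The list passed camera (limma adjusted p = 1.57e-04) and not with an estimated correlation (adjusted p = 0.779). Its score was 0.28 in wild-type replicate 1, above all 3 heterozygous arrays, and the call ended without wild-type replicate 2 or 3 (adjusted p = 0.127 and 0.0962). The median was 0.43 without wild-type replicate 1, 0.09 without wild-type replicate 2 and 0.13 without wild-type replicate 3.

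Circadian clock genes moved in both directions. Of 15 measured members, the activator genes Arntl (146 ± 35.6 and 277 ± 74.3, SD, n = 3 each; log2 0.85) and Npas2 (log2 0.61) rose, and 4 fell when adjusted over the list alone: Dbp (1519 ± 507 and 615 ± 224; log2 -1.29), Per2 (-0.82), Per3 (-0.53) and Tef (-0.44). Per2, Per3 and Tef are named as the rest of those that passed. The list as a whole had a median log2 of -0.19 and passed camera in limma (adjusted p = 0.0303), with adjusted p = 0.612 with an estimated correlation. The call ended without wild-type replicate 2 (adjusted p = 0.143) or heterozygous replicate 1 (0.0595) or 3 (0.102), without the filter (0.437, with a median log2 of -0.10) and without a variance trend (0.0525).

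**Figure D3:**
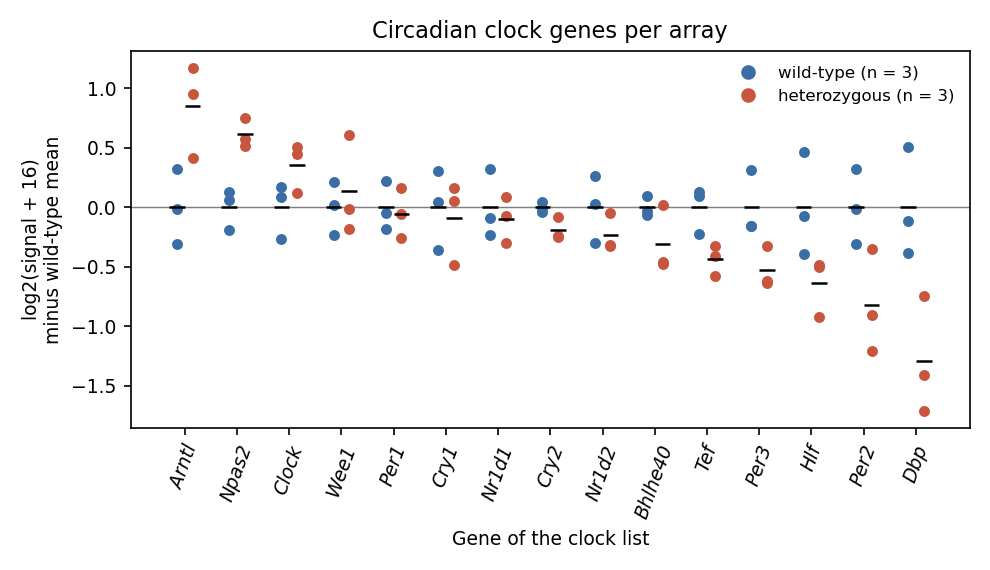
The 15 measured circadian clock genes, each as log2(signal + 16) minus its wild-type mean; points are single arrays (n = 3 per genotype) and black lines are group means. Arntl has the highest heterozygous mean, at 0.85, and Dbp the lowest, at -1.29.

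Lists tied to the function of Mthfd1 did not pass camera. Of 14 measured folate one-carbon genes, Mthfd1 fell adjusted over the list alone and 13 did not pass. Gart had a log2 fold change of 0.37 and Aldh1l1 of -0.27. Other tested probe sets of Gart had 0.76 and 0.02. The folate list passed fry's test for change in either direction (adjusted p = 1.84e-04), the 1 list that did, and this rests on the trapped gene itself: without Mthfd1, a test chosen after seeing the data, the adjusted p was 0.862 over the other 13 genes. The median was 0.07 for 10 purine synthesis genes (camera adjusted p = 0.480, limma), 0.03 for 18 pyrimidine and thymidylate genes (0.663), -0.07 for 15 methionine cycle genes (0.225) and -0.07 for 16 choline genes (0.171). Cbs had a log2 fold change of -0.29, Dut of 0.39 and Uck2 of -0.52, with another probe set of Uck2 of opposite sign. Uck2 was lowest in heterozygous replicate 1, at 158.3, against 250.1 and 283.5 in heterozygous replicates 2 and 3. Below the filter, probe sets of Tap1, Npas2, Top2a and Aldh1l1 also had the opposite sign, with overlapping groups. The serine and ATF4 list (median -0.09), p53 targets (0.00), DNA repair (0.06), Wnt targets (-0.09), apoptosis (0.03), oxidative phosphorylation (0.02) and xenobiotic response (0.05) did not pass camera, with adjusted p between 0.171 and 0.698.

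Among the remaining lists, Il18 (log2 0.45) and Saa3 (0.65) rose and the goblet-cell product Retnlb (-0.45) fell in the antimicrobial list, and the chaperone Hspa8 (0.44) rose while Jund and Hspb1 fell in the immediate early and heat shock list, each adjusted over the list alone; Fasn rose within the adipocyte list. Over all probe sets, the limma adjusted p was 0.636 for Il18, 0.712 for Saa3, 0.752 for Retnlb and 0.344 for Hspa8. Other tested probe sets of Hspa8 had log2 0.70, 0.32 and 0.04, with overlapping groups at 0.32 and 0.04. Retnlb was -0.28 without wild-type replicate 3 and Saa3 0.42 without heterozygous replicate 3. None of these lists passed camera (adjusted p = 0.401, 0.116 and 0.278, limma). Colonocyte (median log2 0.01), goblet (-0.07), enteroendocrine (-0.03), stem cell (0.01), smooth muscle (-0.04), enteric neuron and glia (0.07), fibroblast (-0.01), endothelium (0.03) and B-cell (0.16) markers did not pass either, with adjusted p between 0.0641 and 0.859. The fibroblast list's median and mean were negative and its camera direction was up. Mast cell, exocrine pancreas, red blood cell, skeletal muscle and sex marker lists had fewer than 5 measured genes and medians of -0.05, -0.25, 0.03, 0.30 and -0.07.

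Gene-trap mice can carry a stretch of another strain around the trapped gene, and the genes near Mthfd1 on chromosome 12 were therefore compared with the rest. The 105 measured genes within 20 Mb had a mean absolute t of 0.86, against a median of 0.90 in 10000 random windows (one-sided permutation p = 0.733). A mean over 105 genes can miss a stretch that alters only a few of them. On simulated data the test was tried only with all the near genes shifted by 0.5 log2. Hif1a and Rab15 were lower and Sptlc2 higher at an unadjusted p under 0.05, and 0 of the 105 passed adjusted; Rab15 and Sptlc2 are named as the rest of those 3. A pair of probe sets without a single gene name ranked next after Ifit1 and Rtp4 by p. They read 2972 ± 91.5 and 1726 ± 70.5 (SD, n = 3 each; log2 -0.78, limma adjusted p = 0.0622), and 1283 ± 105 and 653 ± 64.3 (log2 -0.96, adjusted p = 0.0673). Each is annotated with 3 genes, all on chromosome 12 and 21.1 Mb from Mthfd1 in the GRCm38.p6 table, outside that window. They were singled out after their values were seen. No window test held them, since the 40 Mb window used genes with 1 symbol and the count over probe sets used 20 Mb. The window results therefore say nothing about this pair. The first passed with robust variance (limma adjusted p = 0.0385), array weights (0.0403), the ileal covariate (0.0442) and without heterozygous replicate 1 (0.0372). The second passed with robust variance (0.0385) and the ileal covariate (0.0442).

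RNA quality did not separate the genotypes. The ratio of 3' to 5' control signal was 0.707 ± 0.00886 in wild-type and 0.698 ± 0.0375 in heterozygous arrays for Gapdh (SD, n = 3 each; exact permutation p = 0.9) and 1.52 ± 0.0843 and 1.49 ± 0.0489 for Actb (exact permutation p = 0.7). The Y-linked gene Eif2s3y read between 634.4 and 965.6 and Xist between 26.8 and 51.9 in all 6 arrays. Kdm5d and Uty, also Y-linked, read from 371.7 to 452 and from 195.4 to 303.8. By these markers all 6 animals read as male, although the labels do not give sex. Ileal enterocyte genes, a list written after the data were seen, differed in how far they varied within both genotypes. The widest were Apoa1, from 29.5 to 7712, and Fabp6, the ileal bile acid binding protein, from 93.5 to 5662, whereas 5 of the 15 measured varied under 2-fold in signal + 16 between the highest and lowest array, and 1 of these, Dpep1, was highest in wild-type replicate 3 (3584), where Apoa1 and Fabp6 were lowest. The ileal score did not separate the genotypes (0.15 ± 1.10 and -0.15 ± 0.75, SD, n = 3 each; exact permutation p = 0.7).

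**Figure D4:**
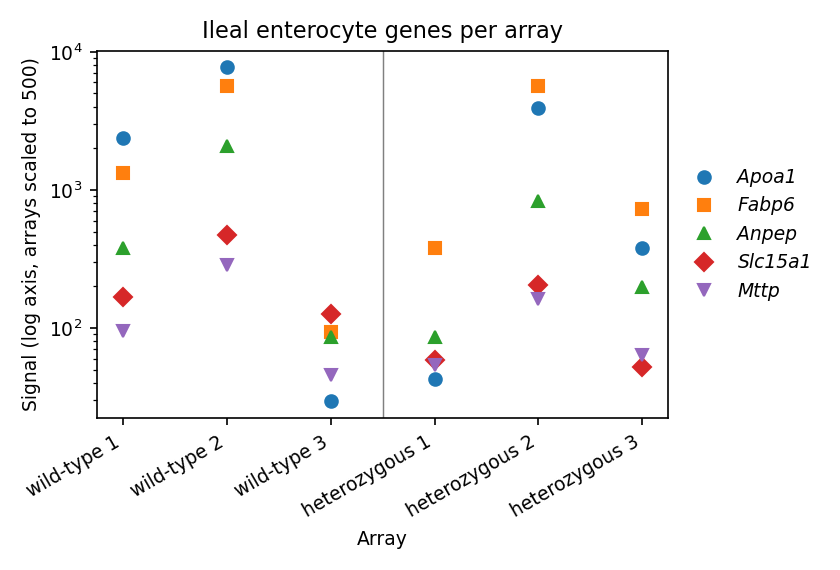
Linear signal, on a log axis, of the 5 ileal enterocyte genes, of 15 measured, with the widest range between arrays, in each of the 6 arrays, with the vertical line parting the genotypes; each point is 1 array. Apoa1 is highest in wild-type replicate 2, at 7712, and lowest in wild-type replicate 3, at 29.5.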

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

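The ileal covariate and the count over probe sets near Mthfd1 were chosen after seeing the data. Mthfd1 stayed lower at its 2 tested probe sets, at log2 -0.73 to -1.09, under every setting that estimated its level again. Neither probe set passed adjusted p 0.05 under those settings. Both were among the probe sets called at the threshold of unadjusted p under 0.01 (limma). The number of probe sets past adjusted p 0.05, 0 in the report, was 2 with median centring, 8 with robust variance, 4 with array weights, 2 with 1 probe set per gene and 8 with the ileal covariate; 8 passed at adjusted p under 0.1 and 193 at unadjusted p under 0.01. Leaving out 1 array gave 0 to 39. Probe sets at unadjusted p under 0.05 numbered 1395 with no filter, 443 at the 60th percentile and 449 with 1 per gene, where fewer or more were tested, and 439 to 1038 with 1 array left out. The lists past the threshold, 8 in the report, numbered 0 with an estimated correlation and 0 with fry; the interferon median of 0.94 then missed the threshold after adjustment over the lists (unadjusted p = 0.029 with an estimated correlation and 0.0224 with fry), and it passed under all other settings. Other settings gave 6 to 12 lists. Near Mthfd1, the mean absolute t of 0.86 ranged from 0.76 to 0.97 with 1 array left out and lay above the random median without wild-type replicate 2 (0.90) or heterozygous replicate 2 (0.87), at one-sided permutation p = 0.428 and 0.417. Unless stated, the cause was not tested.

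The replicate numbers did not pair the arrays steadily: deviations of same-numbered arrays from their group means correlated at -0.12, 0.49 and 0.04. The 0.49 was the highest between any wild-type and heterozygous array, and heterozygous replicate 1 correlated best with wild-type replicate 3 (0.42). Deviations within a group sum to 0, which ties these correlations to each other, so pairing by replicate number is not excluded. With the number as a block, 0 probe sets passed, 921 had an unadjusted p under 0.05 and 9 lists passed.

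Of 1999 values of named genes under other settings, 1966 kept sign and side, 24 passed only there and 9 changed sign, none of them past a threshold. Log2 ranges with 1 array left out were -0.11 to 0.19 for Hba-a2, -0.012 to 0.16 for Eno3, -0.43 to 0.023 for Axin2, -0.19 to 0.17 for Kit, -0.49 to 0.023 for Clps and -0.22 to 0.075 for Eif2s3y. Hba-a2 was -0.0096 with the ileal covariate. Dim probe sets, near the filter, are limited by background, for which no values were used here.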

Other observations

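The tests in this part were chosen after the results were seen, except the counts over other splits of the arrays, which were planned beforehand. Leaving out each array was also a planned setting. Its use to weigh a single animal as the source of the interferon difference was chosen after the results were seen.

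The widest variation in these colons was not between the genotypes. Fabp6 ran from 93.5 to 5662, Apoa1 from 29.5 to 7712 and Anpep, a brush border peptidase, from 85.8 to 2067 between arrays, the 3 widest of 15 ileal genes, where the low values are not shown to be above background, with wild-type replicate 2 and heterozygous replicate 2 high and wild-type replicate 3 and heterozygous replicate 1 low; 5 of the 15 varied under 2-fold in signal + 16, and Dpep1 was highest in wild-type replicate 3. The first principal component held 39.5% of the variance. A split set wild-type replicates 1 and 2 with heterozygous replicate 2 against the rest. It gave 14 probe sets past adjusted p 0.05 and 1298 at unadjusted p under 0.05 (limma), against 0 and 772 for the genotypes. This split was picked as the highest of 10 after all were seen. Wild-type replicates 1 and 3 with heterozygous replicate 1 against the rest gave 0 and 1246. The ileal genes were noticed as leaders of the first component, so the genes, the component and the split come from the same values. With the ileal score as a covariate, 8 probe sets passed (limma adjusted p = 0.0322 to 0.0442), and Mthfd1 did not (0.0861). Those that passed included Ifit1, Rtp4, Rsad2, Tspan4, Dcaf8 and the pair without a single gene name on chromosome 12.

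Several explanations of the ileal variation were weighed, and none was excluded. Tissue cut at different positions along the gut would lower colonocyte genes where ileal genes rise, and over 22 colonocyte genes fixed beforehand the scores instead rose together (Pearson r = 0.95, exact permutation p = 0.00417; Spearman rho = 1, exact permutation p = 0.00278; 6 arrays; adjusted p = 0.00556 over 2 relations; r = 0.905 without wild-type replicate 2 and heterozygous replicate 2), but many of these abundant genes are shared with the small intestine, their scores spanned only -0.19 to 0.18, and no ileum was measured, so a small share of ileum or a shift in position may be the source. A varying share of epithelium would move all epithelial genes alike, and it also stays open, because the median log2 slope of 15 ileal genes on the colonocyte score, 4.45 (95% bootstrap interval over genes 1.22 to 5.53), comes from genes noticed for their wide variation. Whether a few genes set the axis is not decided either by the 36.0% of the variance left on the first component without the list, since leaving out so few genes could hardly alter it. The other relation, the correlation of the ileal score with that component (Pearson r = 0.958, exact permutation p = 0.00556), was computed first and set aside as circular, and no biological explanation was tested.

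Interferon genes were higher in heterozygous colon, and a single animal does not account for it, since the list's median log2 was at least 0.74 with each array left out. Leaving out arrays in turn cannot exclude a difference carried by more than a single animal. The list's score was -0.02, 0.63 and 0.96 in heterozygous replicates 1, 2 and 3. The split of wild-type replicates 1 and 2 with heterozygous replicate 1 against the rest gave an absolute median of 0.78. More macrophages and dendritic cells stay open: their markers moved less (difference of medians -0.67, 95% bootstrap interval over genes -0.97 to -0.44), but their median wild-type signal of 342 against 232 for the interferon genes could hide an added share, and 14 of the 17 were positive. More T cells cannot be told apart from a response in the tissue, because with 7 measured genes the difference was -0.28 (interval -0.99 to 0.88). An infection or exposure shared by the heterozygous animals, housing and genotype may each be the source and were not tested; the labels give no cage or litter.

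Clock activators and outputs differed in opposite directions, by 1.12 in activator minus output score, a division of the list made after that movement was seen, so the score only restates it. Collection at different times of day is a candidate explanation that cannot be told apart from an effect of genotype, because no collection time is recorded in the labels.

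The 6 arrays form 10 splits, too few for a share under 0.05. For probe sets past adjusted p 0.05, the real count of 0 is reached by all 10 of the 10 splits whatever they give, so this count says nothing about chance; the highest other split gave 14. For unadjusted p under 0.05, 4 splits gave at least the real 772 (highest other 1298). For lists past camera, 6 splits gave at least the real 8, and the highest other gave 17, so a count of 8 lists is reached by most groupings of these arrays. The absolute interferon median was 0.94 in the real split, reached by 1 split, with 0.78 as the highest other. For genes near Mthfd1, 6 splits gave a mean absolute t of at least 0.86 (highest other 1.14).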
